A study of Mus musculus with 6 samples.

How the data were processed

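RNA from lenses of 3-month-old mice with the βB2-crystallin W151C knock-in (3 arrays) and wild type (3 arrays) was labelled with Cy3 and hybridised to single-colour Agilent arrays, per the labels. The groups and replicate numbers come from the sample titles, in which the third knock-in array is replicate 4. The deposited values are scanner intensities per spot: the processed signal, background-subtracted within each array by Agilent Feature Extraction 11.0.1.1 per the file headers, and the median spot and background intensity. The submitters' processing notes name version 9.1. Scaling between arrays is not given in the sources used here. The probe design refers to mouse build mm9 per the file headers, so no coordinates are given.

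The log2 of the processed signal was taken and the 75th percentile of each array over its 43020 non-control spots subtracted. Spots marked as non-uniform or population outliers were left out, and spots of a probe were averaged. A probe counted as well above background on an array if at least 50% of its spots did, and was kept if this held on all arrays of at least 1 group, leaving 21076 of 39429 probes. The files give accessions and no symbols; 27234 probes were named through RefSeq accessions (without versions) in a table of assembly GRCm38.p6, giving 20659 symbols. The probe with the highest mean represented each of 12785 genes. Genes were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, knock-in minus wild type, 4 residual degrees of freedom), with Benjamini-Hochberg adjustment. Where a gene was not well above background in a whole group, the fold is a lower bound, taken against, per array, the higher of the lowest signal among probes well above background and the probe's own. Such a bound holds for the probe that represents the gene.

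Gene lists were fixed before the data were examined (35 lists, 786 genes; 34 with at least 5 measured genes tested, the sex chromosome list only described). They were tested with camera at a preset correlation of 0.01, also with an estimated correlation and fry. The genes named are all crystallins, the 12 largest rises and 12 largest falls among genes past the threshold whose arrays separate by genotype, and up to 4 members with the smallest p per described list; genes outside this rule are said to be named after their values were seen. Some genes that the rule takes are not reported here. A log2 fold change of 1 is 2-fold.

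Replicates of a group were compared on 399 probes with 10 or more spots: wild type arrays 1 and 2 differed by over 2 standard errors in 39.1% of them, and correlated at 0.996 over genes. This shows that they are not the same values, and does not show whether they come from separate animals. Xist and Y-linked transcripts were both well above background on every array, so pools of animals are not ruled out, and n = 3 then counts pools. Each array was counted as a sample because the labels call it a biological replicate, and p-values measure the spread between arrays, which may be technical. Slide and scan day were tested as blocks, slide as a random block with a consensus correlation of 0.56. Alternatives covered scaling (quantile, median), background (normexp, offset 50), filters, flags, array weights, the mean of a gene's probes, blocks and leaving out each array. Normexp had been planned on mean signals and was run on median signals. The procedure was tested on simulated data for 12785 genes in 3 against 3 arrays: it recovered 31% of 2-fold and 83% of 4-fold changes, with 5 false calls among 119. The simulation changed 200 genes and drew each array independently, with no effect of slide or day. Its rates therefore need not hold for these arrays, where slide and genotype go together and many more genes were called. Probes without a gene name were left out of comparisons by gene.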

Results

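RNA was measured in lenses of mice at 3 months of age. The knock-in animals carried the W151C change, tryptophan to cysteine at codon 151 of βB2-crystallin, made by genome editing of the Crybb2 gene. βB2-crystallin is an abundant structural protein of the lens. There were 3 knock-in arrays (labelled replicates 1, 2 and 4) and 3 wild type arrays (replicates 1, 2 and 3), each a single-colour array of 39429 different probes. The labels call them biological replicates, and whether an array held the lenses of 1 animal or of several is not stated in the labels. The 75th percentile of the spot signal was 167, 201 and 188 on knock-in arrays 1, 2 and 4, 142 and 120 on wild type arrays 1 and 2, and 698 on wild type array 3. Between 45.5% and 58.4% of spots were well above background, and no spot carried a saturation flag. The number of arrays limits the precision, and an exact permutation test of 3 against 3 cannot go below p = 0.1, so genes were tested with limma.

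All 3 knock-in arrays lay on slide 1, wild type arrays 1 and 2 on slide 2, and wild type array 3 on slide 3. Slides 1 and 2 were scanned on the same day and slide 3 on another day. Values within the shared day, which set the knock-in arrays against wild type arrays 1 and 2, and values with slide as a random block stand beside the results below. Single genes outside the crystallins are given a random-block value where it ends the call. The list test sets a list's genes against all others, so a block that weakens most genes alike need not weaken a list.

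The comparison of knock-in with wild type lenses asked which transcripts differ in level when βB2-crystallin carries the substitution. Interferon response genes were higher in the knock-in lenses, with 15 of 18 past the test and a median log2 fold change of 1.35, and so were genes of fibrosis and the epithelial to mesenchymal transition (EMT), with 11 of 17 and a median of 1.55. Lens fibre cell genes and cytosolic ribosomal protein genes were lower, with 12 of 23 and 14 of 41 past the test and medians of -0.68 and -0.55. With an estimated correlation between genes none of these lists was called (adjusted p = 0.11, 0.352, 0.11 and 0.86 with an estimated correlation, in that order). The estimates were 0.033, 0.050, -0.030 and 0.57. For fibre genes the estimate lay below the preset 0.01, so correlation does not account for the lost call there. In this setting camera also takes p from the 4 residual degrees of freedom, which raises p at any correlation.

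Crybb2 itself, the edited gene, had a mean log2 signal of 8.96 ± 0.20 (SD, n = 3) in knock-in and 9.37 ± 1.22 (SD, n = 3) in wild type lenses, relative to the 75th percentile of each array. Its values were 9.17, 8.91 and 8.79 on knock-in arrays 1, 2 and 4, 9.94 and 10.19 on wild type arrays 1 and 2, and 7.96 on wild type array 3. The difference of -0.41 (SE 0.55, adjusted p = 0.625) did not pass the test, and both Crybb2 probes had a negative difference. A substitution need not change the level of its transcript, so this value does not check the labels. The result depended on each of the wild type arrays. Without array 3 the difference was -1.11 (adjusted p = 0.00435), within the scan day fitted as a block it was -1.11 (adjusted p = 0.00403), without array 2 it was 0.0056 (adjusted p = 0.995) and without array 1 it was -0.12 (adjusted p = 0.914). With slide as a random block it was -0.19 (adjusted p = 0.919) and after quantile normalization -0.013 (adjusted p = 0.954). Crybb2 lay near the brightest signal of most arrays, at 139566 against a maximum of 141459 on wild type array 1. Quantile normalization gives the top ranks the same values on every array. It therefore holds the Crybb2 difference near 0 and cannot decide whether its level fell. Over all alternative settings the adjusted p lay between 0.00403 and 0.995, leaving aside array weights (6.02e-08), a fit that rests in effect on 1 array against 1.

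Among the crystallins, the main structural proteins of the lens, 15 of 16 had a lower mean in the knock-in lenses, and Crygn was the exception. After quantile normalization Cryaa, Cryab and Cryba1 turned to 0.57, 0.14 and 0.21, and after normexp with quantile normalization these and Crybb2 were positive. These genes are among the brightest on the arrays, where quantile normalization can hide a shared fall, so their turn does not decide the direction. The falls of Crybb1 by 1.51 on the log2 scale (SE 0.20, adjusted p = 0.00298), Crygb by 2.29 (SE 0.43, adjusted p = 0.0103) and Cryba4 by 1.38 (SE 0.39, adjusted p = 0.0411) passed the test over all genes. A total of 5 crystallins passed when adjusted over the list alone. Differences that did not pass were -1.91 (SE 0.58, adjusted p = 0.0517) for Cryge, -1.83 (SE 0.56, adjusted p = 0.0528) for Cryga, -2.25 (SE 0.90, adjusted p = 0.111) for Crygf, -1.54 (SE 0.58, adjusted p = 0.0933) for Crygc and -1.41 (SE 0.57, adjusted p = 0.115) for Crygd. The remaining β-crystallins differed by -0.34 (Cryba1), -0.67 (Cryba2) and -0.51 (Crybb3), and the α-crystallins, small heat shock proteins that act as chaperones, by -0.17 (Cryaa) and -0.26 (Cryab). Crygs differed by -0.60 and Crygn by 0.69, and none of these passed. Genes of the γ-crystallin family are close in sequence, so probes can bind each other's transcripts and single members are uncertain. The call of Cryba4 was lost on leaving out single arrays, with adjusted p from 0.0876 to 0.123 without knock-in 1, knock-in 2, knock-in 4, wild type 1 or wild type 2.

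The spread came mainly from wild type array 3, where the crystallins after scaling lay below wild type arrays 1 and 2 by a median of 2.09 on the log2 scale, while before scaling 14 of 16 were higher there. In scaled values the SD was larger in wild type than in knock-in lenses for all 16. Within the shared scan day, 15 of 16 crystallins fell, with a median of -1.53, from -3.42 for Crygf to -0.88 for Cryab, and Crygn at 0.43 did not pass. With slide as a random block only Crybb1 passed (adjusted p = 0.0435), against adjusted p = 0.0748 for Crygb and 0.242 for Cryba4. As a list the crystallins were lower (median -1.03, camera adjusted p = 0.0482; adjusted p = 0.86 with an estimated correlation; adjusted p = 5.53e-07 within the scan day; adjusted p = 0.0517 with slide as a random block). After quantile normalization, which can hide a shared fall of the brightest probes, the median was -0.53 (camera adjusted p = 0.0852). Leaving out 1 array also ended the call of crystallins (adjusted p from 0.0522 to 0.164 without knock-in 2, knock-in 4, wild type 1 or wild type 2), and over all alternatives the adjusted p lay between 5.53e-07 and 0.86.

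**Figure D1:**
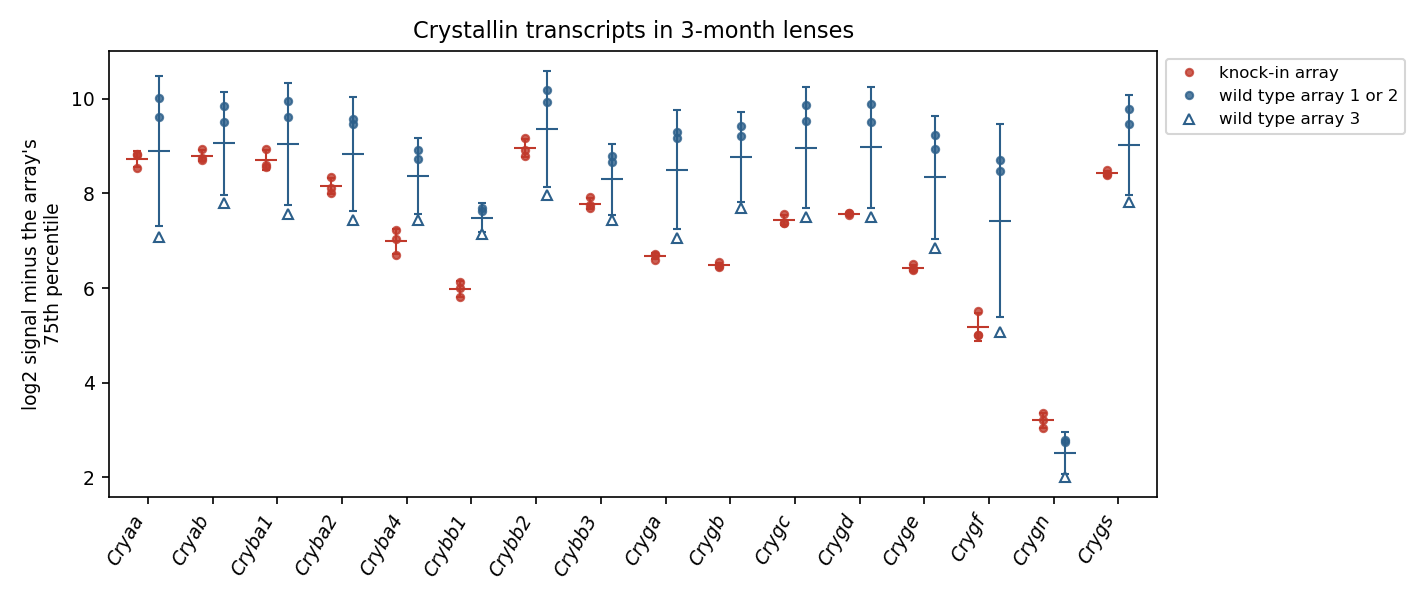
Normalized log2 signal of the 16 crystallins, with each array as a point (knock-in red, wild type arrays 1 and 2 blue, wild type array 3 an open triangle) and bars for the mean and SD of 3 arrays. For Crybb2, the knock-in arrays lie between 8.79 and 9.17, below wild type arrays 1 and 2 and above wild type array 3 at 7.96.

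Of 12785 genes tested, 3312 passed an adjusted p of 0.05, 1697 higher and 1615 lower in knock-in lenses, and 1841 of them by at least 2-fold (843 higher, 998 lower). The excess of 2-fold falls depended on the filter. It was 948 higher and 754 lower without the filter on dim probes, and 631 and 604 with probes above background on all arrays. Of the 1841 genes, 223 were not above background in knock-in and 96 in wild type. The calls were 51.2% higher, against 40.9% higher (1143 of 2798) when arrays were centred on their median. Of the 12785 genes, 45.9% had all knock-in arrays on one side of all wild type arrays, where chance gives 10%. The count was 620 with slide as a random block, every one of them at least 2-fold, and 5566 with the scan day as a block. It was 1538 without knock-in replicate 2, 1699 without wild type replicate 1, 1862 without wild type replicate 2 and 5661 without wild type replicate 3. No slide held both genotypes, so slide and genotype cannot be told apart. Within the shared day each genotype lay on its own slide. The random block takes the spread between slides of a genotype from wild type array 3 alone, which also differed in scan day.

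Among the largest rises, Fn1, which encodes fibronectin, rose by 7.19 on the log2 scale (SE 0.25, adjusted p = 3.79e-05), and Tgfbi, a matrix protein induced by TGF-β, by 6.24 (SE 0.19, adjusted p = 2.38e-05). Trib3, a pseudokinase induced in the integrated stress response, rose by 6.44 (SE 0.29, adjusted p = 5.24e-05), and Asns, asparagine synthetase, by 6.24 (SE 0.39, adjusted p = 0.000197). Prss23, a serine protease, rose by 6.01. Of the wild type arrays, Fn1 and Trib3 were well above background on 2 and Prss23 on 1, so the sizes of these rises are set partly against background. Other genes were not well above background on any wild type array and have only bounds. Gpnmb, a transmembrane glycoprotein, was at least 37.2-fold higher in knock-in lenses (adjusted p = 0.000131). The bounds were at least 28.5-fold for Emp1, at least 27.1-fold for Fst, the activin-binding protein follistatin, at least 23.5-fold for Bcl3, an IκB family protein, at least 22.0-fold for Cdkn1a, the cell cycle inhibitor p21, and at least 14.6-fold for Extl1.

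The largest falls included Rgs4, a regulator of G protein signalling, at -5.88 (SE 0.26, adjusted p = 4.85e-05), and Birc7, an inhibitor of apoptosis family member on the lens fibre list, at -5.24 (SE 0.24, adjusted p = 5.64e-05). Tcp11 fell by 4.81, Plekha4 by 4.52, Trhr2, a receptor for thyrotropin-releasing hormone, by 4.58, Klhl35 by 4.56 and the class I histocompatibility gene H2-Q10 by 4.56 on the log2 scale, with adjusted p from 3.79e-05 to 0.0019. Of the knock-in arrays, Rgs4 and Klhl35 were well above background on 2 and H2-Q10 on 1, so the sizes of these falls are set partly against background. Wdfy4, Gp2 and Pax4 were not well above background on any knock-in array and were at least 28-fold, 25.6-fold and 14.2-fold lower. Mapk4, with no knock-in array well above background, passed the test (adjusted p = 0.000169), but its 2 probes differed in the size of the fall, so no bound is given. Where the other probe was taken, without wild type 1 or wild type 2, its value was -0.87 or -0.86 (adjusted p = 0.115 or 0.105). With slide as a random block H2-Q10 did not pass (adjusted p = 0.0581).

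**Figure D2:**
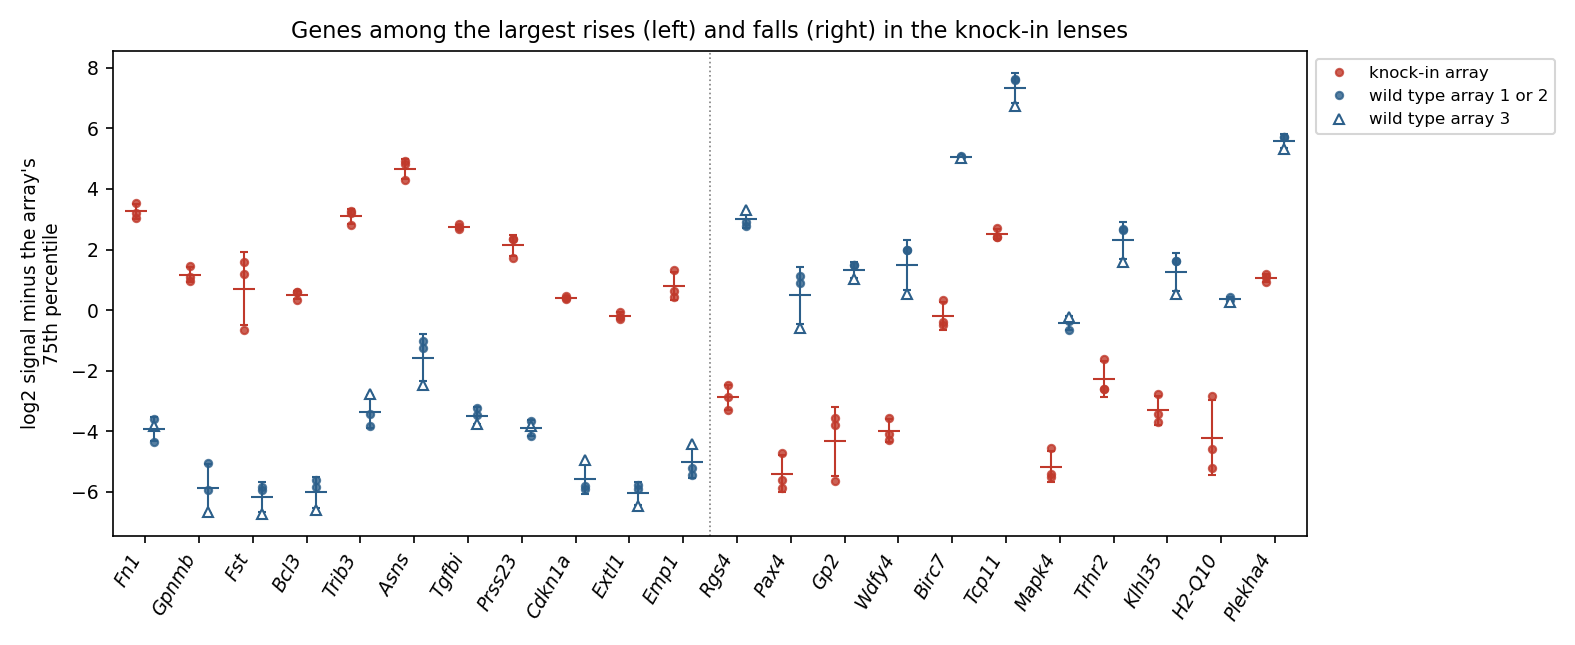
Normalized log2 signal of 11 of the 12 genes with the largest rises and 11 of the 12 with the largest falls among genes past the test whose arrays separate by genotype, with points for arrays and bars for the mean and SD of 3 arrays. Fn1 averages 3.26 in knock-in and -3.93 in wild type lenses, and Birc7 -0.19 and 5.05.

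Of 34 gene lists tested, 6 were called, 3 higher (interferon response, fibrosis and EMT, cell cycle) and 3 lower (crystallins, lens fibre cell genes, ribosomal proteins). None of the 6 was called with an estimated correlation between genes, and the number called was 10 without wild type replicate 2. The estimated correlation was 0.98 for crystallins and -0.021 for cell cycle, and that setting rests on the 4 residual degrees of freedom. Fry, which asks whether a list's genes move one way on balance, called 14. Splitting the 6 arrays into 3 and 3 in all 10 ways gave at least 6 lists in 6 of them, the real split included, and up to 8. The number of lists called therefore did not single out the real split. Every other split mixes the genotypes unevenly and keeps part of their difference, so these counts cannot decide whether the lists set the genotypes apart. Of 144 named genes that passed, 61 also passed with slide as a random block and 142 with the scan day as a block.

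Lens fibre cell genes fell, with 12 lower and none higher of 23 measured (14 lower adjusted over the list alone; median -0.68, camera adjusted p = 8.35e-06; adjusted p = 0.11 with an estimated correlation). Lctl, a klotho family member, fell by 2.38 (SE 0.21, adjusted p = 0.000614), Lim2, a fibre membrane protein, by 2.35 (SE 0.21, adjusted p = 0.000634) and Cdkn1c, a cell cycle inhibitor of differentiating fibre cells, by 1.71 (SE 0.15, adjusted p = 0.000536). Mip, the fibre water channel aquaporin 0, named after its value was seen, fell by 1.21 (SE 0.35, adjusted p = 0.045). Lens epithelial genes were not called as a list (median -0.38, camera adjusted p = 0.313): 1 higher and 3 lower of 17 measured (1 higher and 3 lower when adjusted over the list alone), the rise being Pdpn, podoplanin, at 1.55 (SE 0.15, adjusted p = 0.00077), and the falls Aqp5 at -1.66, Foxe3 at -1.11 and Gas6 at -0.59. Leaving out 1 array ended the calls of Mip (adjusted p from 0.114 to 0.136 without knock-in 1, knock-in 2, knock-in 4, wild type 1 or wild type 2). It also ended those of Foxe3 (adjusted p from 0.0518 to 0.0537 without knock-in 1, knock-in 4 or wild type 2) and Gas6 (adjusted p from 0.0631 to 0.118 without knock-in 1, knock-in 2, knock-in 4, wild type 1 or wild type 2). Foxe3 was well above background on 2 knock-in arrays. None of these 3 calls passed with slide as a random block (adjusted p = 0.238 for Mip, 0.158 for Foxe3 and 0.236 for Gas6).

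Genes of fibrosis and the epithelial to mesenchymal transition rose, with 11 higher and 3 lower of 17 measured (11 higher and 3 lower when adjusted over the list alone; median 1.55, camera adjusted p = 0.0014; adjusted p = 0.352 with an estimated correlation). The collagen genes Col1a1 and Col5a1 rose by 5.06 (SE 0.46) and 2.34 (SE 0.18), beside Fn1 and Tgfbi. The list was also not called with probes above background on all arrays (median 1.03, adjusted p = 0.0762) or with array weights (adjusted p = 0.0767), and with normexp its median was 0.68. Over all alternatives the adjusted p lay between 3.89e-06 and 0.352. The falls, named after their values were seen, were Acta2, the smooth muscle actin of myofibroblasts, at -2.24 (SE 0.32, adjusted p = 0.00373), Vcan at -1.65 and Tgfb3 at -0.84. The probes of Vcan disagreed, and their mean gave 0.045. Calls that single arrays decided were those of Vcan (adjusted p from 0.0751 to 0.0942 without knock-in 1, knock-in 2, knock-in 4, wild type 1 or wild type 2) and Tgfb3 (adjusted p from 0.0626 to 0.0713 without knock-in 1, knock-in 4, wild type 1 or wild type 2). The 3 falls did not pass with slide as a random block (adjusted p = 0.0586 for Acta2, 0.193 for Vcan and 0.212 for Tgfb3).

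Interferon response genes rose, with 15 higher and 1 lower of 18 measured (16 higher and 1 lower when adjusted over the list alone; median 1.35, camera adjusted p = 5.71e-08; adjusted p = 0.11 with an estimated correlation). B2m, the light chain of class I histocompatibility molecules, rose by 3.40 (SE 0.32, adjusted p = 0.00072) and Usp18, an interferon-induced protease, by 1.47 (SE 0.15, adjusted p = 0.000926). Gbp3 and Oas1a were at least 3.98-fold and 3.02-fold higher, being not well above background in wild type. The exception that fell was Ifit2 at -1.12, named after its value was seen. Its call was lost on leaving out single arrays, Ifit2 (adjusted p from 0.058 to 0.102 without knock-in 2, knock-in 4 or wild type 1). The list's median was the same with its 3 genes below background in wild type at their bound, and 0.75 with normexp. Leukocyte markers were not called (camera adjusted p = 0.594; 2 higher and 1 lower of 15 measured, 2 higher and 1 lower when adjusted over the list alone). Among the knock-in arrays, the 10 of them well above background on all arrays lay higher on array 1 than on the others, by a median of 0.84. On knock-in arrays 1 and 2 these 10, which leave out Tyrobp and C1qc, differed from wild type by a median of -0.23, and all 27 markers by 0.97. Many of the 27 were not well above background, and the lowest gene signal was -5.07 and -6.04 on knock-in arrays 1 and 2 against -6.23, -6.09 and -6.76 on the wild type arrays. Of the 15 measured, the rises were Tyrobp, an immune adaptor protein, at least 5.11-fold (adjusted p = 0.00291), and C1qc, a complement component made by macrophages, at 4.39 (SE 0.82, adjusted p = 0.00977), well above background on 1 wild type array. Itgam, an integrin of myeloid cells, fell by 1.65 (adjusted p = 0.0404), but 1 of its 3 probes was higher and single arrays ended the call of Itgam (adjusted p from 0.0815 to 0.135 without knock-in 1, knock-in 2, knock-in 4, wild type 1 or wild type 2). With slide as a random block Ifit2, Tyrobp, C1qc and Itgam did not pass (adjusted p = 0.174, 0.0693, 0.0919 and 0.238).

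Cell cycle genes were called higher (median 0.51, camera adjusted p = 0.0482; adjusted p = 0.352 with an estimated correlation), with 10 higher and 2 lower of 23 measured (12 higher and 3 lower when adjusted over the list alone). Mki67, a marker of cycling cells, rose by 1.71 (SE 0.22, adjusted p = 0.00233), Rrm2 by 1.17 and Kif20a by 1.08. Kif20a was well above background on 2 wild type arrays. Of the 2 genes counted as lower, Aurka stood at -0.68, named after its value was seen. Tpx2 is given no fold, because the probe that represents it was not well above background on any knock-in array and its other probe went the opposite way. That other probe was taken without wild type 1, 2 or 3, and the direction turned. Leaving out 1 array ended the call of Aurka (adjusted p from 0.108 to 0.179 without knock-in 2, knock-in 4, wild type 1 or wild type 2) and that of the list, cell cycle (adjusted p from 0.0522 to 0.0648 without knock-in 2 or knock-in 4). The list was called in 11 of 22 alternatives, with adjusted p from 0.00271 to 0.352. Cytosolic ribosomal proteins fell, with 14 lower and none higher of 41 (17 lower adjusted over the list alone; median -0.55, camera adjusted p = 9.74e-07; adjusted p = 0.86 with an estimated correlation), including Rpl28 at -1.25 and Rpl18 at -0.92. After quantile normalization the ribosomal median was -0.23 (adjusted p = 0.0356; 8.01e-13 to 0.86 over all alternatives), and the cell cycle median was 0.31 after normexp with quantile normalization. Within the scan day all 6 lists were called, with adjusted p of 3.17e-05 for fibre genes, 0.0084 for fibrosis, 1.44e-06 for interferon, 0.0492 for cell cycle and 4.7e-07 for ribosomal proteins. With slide as a random block these were 4.05e-06, 0.000204, 7.63e-09, 0.0396 and 1.31e-05, with Rrm2, Kif20a, Tpx2, Aurka and Rpl18 not past the test (adjusted p = 0.0763 for Rrm2, 0.123 for Kif20a, 0.0919 for Tpx2, 0.365 for Aurka and 0.134 for Rpl18). Single genes past it numbered 4 lower fibre genes, 5 higher fibrosis genes, 6 higher interferon genes, 1 higher cell cycle gene and 1 lower ribosomal protein gene. The random-block p-values of the lists, which set list genes against all others, do not carry the uncertainty from slides as those of single genes do.

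The unfolded protein response list was not called (median 0.048, camera adjusted p = 0.58), with 6 higher and 4 lower of 25 measured (7 higher and 5 lower when adjusted over the list alone). The members that rose were Trib3, Asns, Chac1, a glutathione-degrading enzyme, at 4.40 (SE 0.25, adjusted p = 0.000144), the transcription factor genes Ddit3 at 1.60, Atf6 at 1.62 and Atf4 at 0.88. Herpud1, Creld2, Xbp1 and the chaperone gene Hsp90b1 fell by 1.13, 1.16, 0.70 and 0.60. Atf6, Atf4 and these 4 were named after their values were seen, and Atf6 was well above background on 1 wild type array. Calls lost on leaving out 1 array were those of Atf6 (adjusted p from 0.0525 to 0.0662 without knock-in 1, knock-in 2, knock-in 4 or wild type 1) and Atf4 (adjusted p from 0.0708 to 0.0951 without knock-in 2, knock-in 4, wild type 1 or wild type 2). Further ones were those of Xbp1 (adjusted p from 0.0631 to 0.0766 without knock-in 2, wild type 1 or wild type 2) and Hsp90b1 (adjusted p from 0.0832 to 0.133 without knock-in 1, knock-in 2, knock-in 4, wild type 1 or wild type 2). With slide as a random block Ddit3, Atf6 and Atf4 did not pass (adjusted p = 0.0771 for Ddit3, 0.165 for Atf6 and 0.209 for Atf4), nor did the 4 falls (adjusted p = 0.11 for Herpud1, 0.0741 for Creld2, 0.186 for Xbp1 and 0.224 for Hsp90b1).

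Genes of retinal photoreceptors stood apart on knock-in array 4. The 22 photoreceptor genes lay there above knock-in arrays 1 and 2 by a median of 4.17, 18 of them by at least 1, while the median over all genes tested was 0.0054. The 6 of them well above background on all arrays lay there higher by a median of 2.10, and on knock-in arrays 1 and 2 they differed from wild type by a median of 0.21. All 22 genes, in part not well above background there, differed from wild type on these 2 arrays by a median of 1.54, and the measured genes of the list had a median of 1.57 without knock-in 4. The list was not called between genotypes (median 2.16, camera adjusted p = 0.089; 3 higher and 0 lower of 10 measured, 5 higher and 1 lower when adjusted over the list alone). It was called on leaving out single arrays, photoreceptors and retina (adjusted p from 0.00952 to 0.037 without knock-in 1, knock-in 2, knock-in 4 or wild type 2). Over all alternatives the adjusted p lay between 0.00065 and 0.86. Retinal glia genes (median 1.39, camera adjusted p = 0.195; 3 higher and 0 lower of 8 measured, 5 higher and 1 lower when adjusted over the list alone) were called without wild type 2 (median 1.64, adjusted p = 0.043) and included Gfap, an intermediate filament of astrocytes and reactive Müller cells, at 3.43 (SE 0.24, adjusted p = 0.000262), well above background on 2 wild type arrays. Gfap stood at 0.42, 0.26 and -0.06 on knock-in arrays 1, 2 and 4, so its rise did not come from knock-in array 4.

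**Figure D3:**
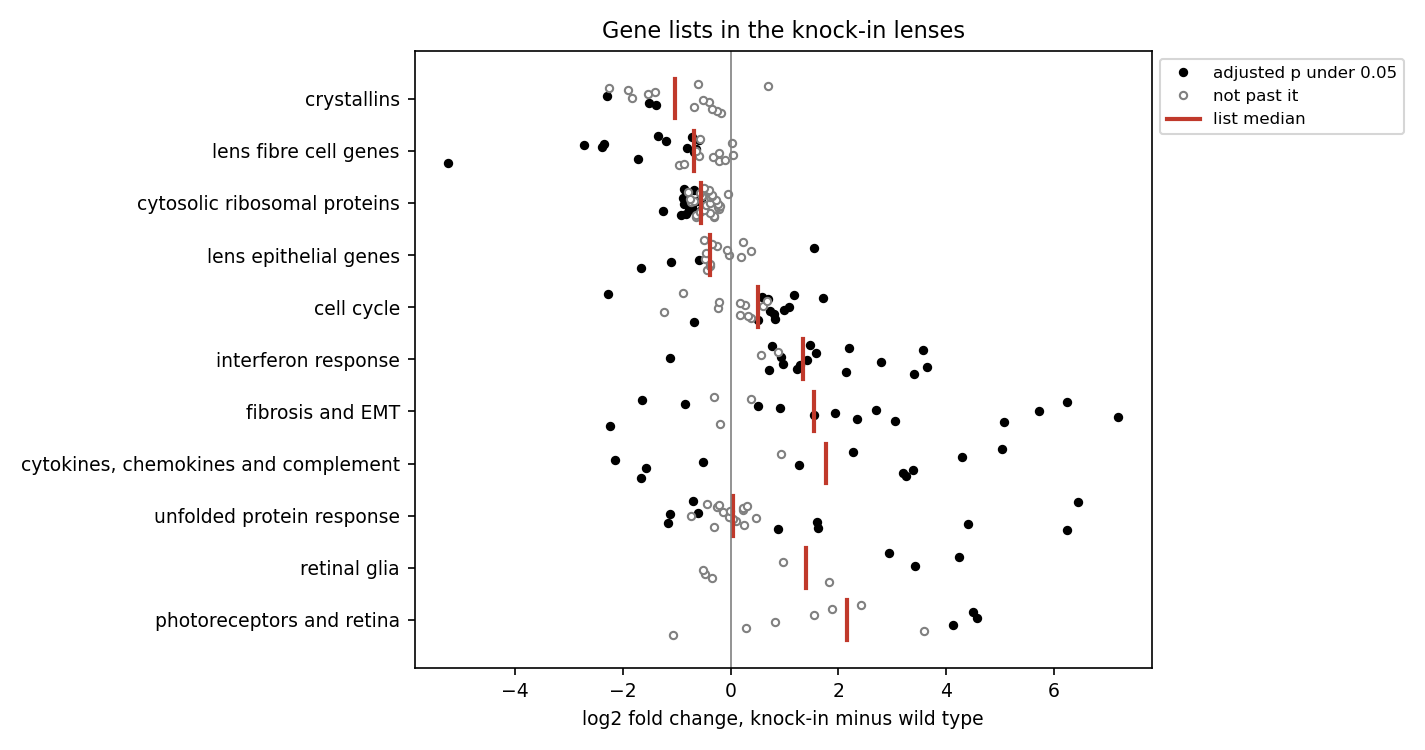
Log2 fold change, knock-in minus wild type, of each measured gene in 11 lists, with filled points for genes past an adjusted p of 0.05, open points for the others and a red line at each list's median; genes below background in a group are at their fitted value. The medians run from -1.03 for crystallins to 2.16 for photoreceptors.

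**Figure D4:**
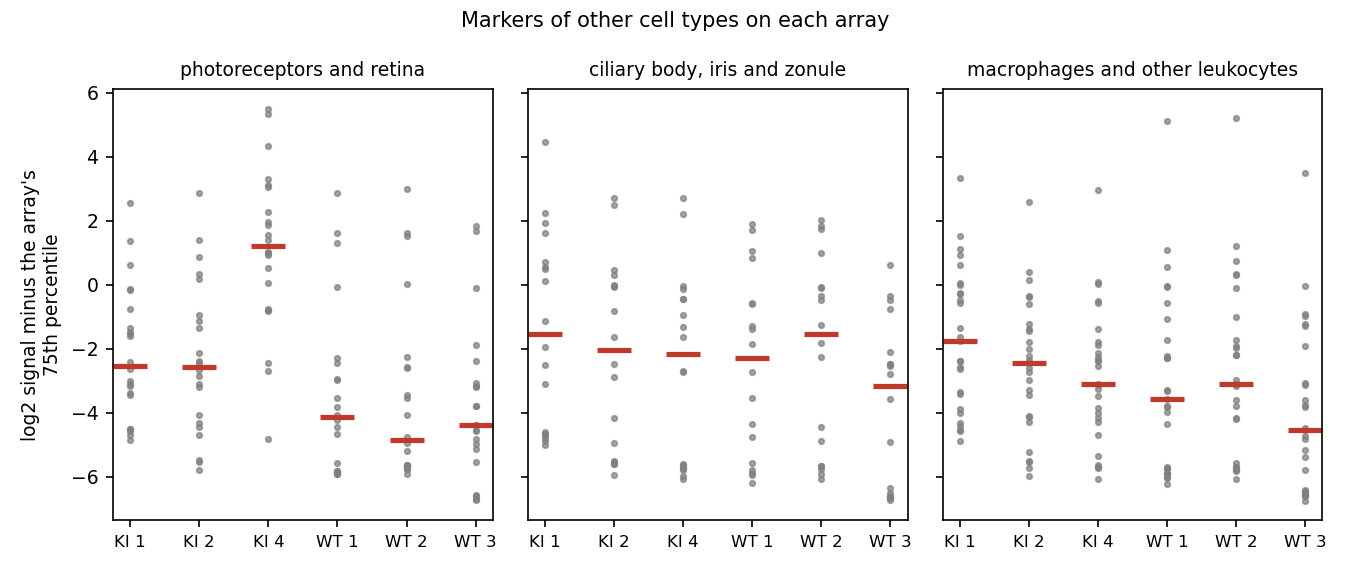
Normalized log2 signal of photoreceptor, ciliary and leukocyte markers on each array, with grey points for genes, including those not well above background, and a red line at the median. The photoreceptor median is 1.21 on knock-in array 4 and -2.53 and -2.55 on knock-in arrays 1 and 2.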

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

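The rule for signals outside the main measurement picked out the probes that could not be given a gene name and so entered none of the comparisons by gene. Of 5116 such probes that were measured above background, 887 differed between the genotypes at an adjusted p of 0.05 (limma), 245 higher and 642 lower in knock-in lenses. They carry no gene name here, and no explanation was tested. They passed the filter that asks for signal above background in at least 1 group. The balance of higher and lower named genes changed with that filter, and this was not checked for the unnamed probes. The rule for outlying samples does not apply to groups of 3, and there is no second contrast to set beside this one.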

How the results depend on the processing

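Normexp on median signals and the fit with neither of the arrays that stand apart (knock-in 4 and wild type 3) were chosen after seeing the data, the others before the data were examined. Normexp on mean signals was not run, since the deposited values hold the median spot signal and no mean signal. The cause was not tested for any value below unless stated. The 3312 changed genes became 1433 (normexp on median signals, 75th percentile), 2002 (no filter on dim probes), 11871 (array weights), 620 (slide as a random block), 5566 (scan day as a fixed block), 5446 (replicate block), 6072 (2 against 2, neither of the arrays that stand apart), 5053 (unadjusted p under 0.05), 4970 (probes instead of genes). Leaving out an array gave 1538 to 5661. The array weight fit is in effect 1 array against 1, with weights of 93.5 for knock-in 2, 20.6 for wild type 1 and at most 0.548 for the others, and its iterations stopped early. The 1841 genes at least 2-fold changed became 786 (normexp on median signals, 75th percentile), 945 (normexp on median signals, quantile normalization), 620 (slide as a random block), 2768 (replicate block), 2849 (2 against 2, neither of the arrays that stand apart), 2857 (probes instead of genes). They were 1359 to 2629 with an array left out. Crybb2, at -0.41, became 0.15 (normexp on median signals, quantile normalization), -1.03 (array weights), -1.11 (scan day as a fixed block), -1.02 (replicate block), -1.02 (2 against 2, neither of the arrays that stand apart). It was -0.013 with quantile normalization, -0.13 with normexp and the 75th percentile, -0.19 with slide as a random block and -1.11 to 0.0056 with an array left out. The 6 lists became 0 (camera with an estimated correlation), 14 (fry); 5 to 10 with an array left out. Interferon, fibre and ribosomal lists were called in 21 of 22 alternatives each, all but the estimated correlation, fibrosis (not with probes above background on all arrays, array weights or the estimated correlation) in 19 of 22, crystallins in 14 of 23 and cell cycle in 11 of 22. These alternatives are not independent. The scan day block compares the same arrays as the fit without wild type 3, and the replicate block the same as the fit of 2 against 2. The replicate block (numbers 1 and 2 are shared) gave 5446 genes. Deviations from the group means correlated at 0.17 for number 1 and -0.22 for number 2 across genes. Unlike numbers gave much the same, 0.22 for knock-in 1 with wild type 2 and -0.18 for knock-in 2 with wild type 1. This check therefore shows no pairing by number and cannot exclude one.

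Of 144 named genes that passed, 61 also passed with slide as a random block, 142 with the scan day as a block and 139 after quantile normalization. With normexp and the 75th percentile 96 passed, and 58 of the 144 moved by over 1.5 times. With normexp and quantile normalization 130 passed, and 66 moved by over 1.5 times. The following genes changed direction. Cryaa gave 0.57 (quantile normalization), 0.44 (normexp on median signals, quantile normalization), 0.12 (slide as a random block), -1.08 to 0.39 with an array left out. Cryab gave 0.14 (quantile normalization), 0.11 (normexp on median signals, quantile normalization), -0.88 to 0.14 with an array left out. Cryba1 gave 0.21 (quantile normalization), 0.22 (normexp on median signals, quantile normalization), -1.08 to 0.11 with an array left out. Junb gave 0.055 (normexp on median signals, 75th percentile). Crybb2 gave 0.15 (normexp on median signals, quantile normalization), -1.11 to 0.0056 with an array left out. Atp1b3 gave 0.14 (normexp on median signals, quantile normalization). Smad1 gave 0.22 (probes above background on all arrays). Hba-a2 gave -0.11 (array weights). Vcan gave 0.045 (mean of a gene's probes). Tpx2 gave -2.65 to 2.46 with an array left out. Tpx2 turned because its probes disagree and another one was taken, and both ends of its range rest on a probe not well above background in 1 genotype. No list was called in a setting that turned its test, but elsewhere immediate early genes were called in 4 of 22 alternatives, retinal glia in 3, and heat shock, autophagy and p53 lists with fry. The medians, which can keep their sign, were as follows. Glycolysis gave 0.11 (quantile normalization), 0.28 (normexp on median signals, quantile normalization), 0.088 (replicate block), 0.088 (2 against 2, neither of the arrays that stand apart), -0.11 to 0.078 with an array left out. Mitochondrial respiratory chain gave 0.031 (quantile normalization), 0.057 (normexp on median signals, quantile normalization), -0.092 (replicate block), -0.092 (2 against 2, neither of the arrays that stand apart). Cytosolic heat shock proteins gave 0.070 (normexp on median signals, 75th percentile), 0.085 (no filter on dim probes), -0.013 (array weights). Proteasome subunits gave -0.082 (normexp on median signals, 75th percentile), -0.091 (no filter on dim probes), -0.091 (probes above background on all arrays), -0.10 (slide as a random block), -0.093 to 0.0093 with an array left out. Calcium handling gave -0.034 (normexp on median signals, 75th percentile), -0.0087 (no filter on dim probes), -0.11 (probes above background on all arrays), -0.085 (array weights), -0.13 (scan day as a fixed block), -0.17 (replicate block), -0.27 (2 against 2, neither of the arrays that stand apart), -0.042 (fry), -0.15 to 0.062 with an array left out. TGF-beta and BMP signalling gave 0.026 (normexp on median signals, 75th percentile), 0.13 (no filter on dim probes), 0.075 (probes above background on all arrays). Erythroid cells gave -0.070 (normexp on median signals, 75th percentile), 0.66 (no filter on dim probes), -0.72 to -0.23 with an array left out. Autophagy and lysosome gave -0.020 (no filter on dim probes). Blood vessel endothelium gave 0.63 (no filter on dim probes), -0.65 to -0.17 with an array left out. P53 targets and apoptosis gave 0.13 (probes above background on all arrays). Macrophages and other leukocytes gave -0.39 (probes above background on all arrays), -0.50 (array weights), -0.58 (scan day as a fixed block), -0.31 to 0.37 with an array left out. Retinal glia gave -0.34 (probes above background on all arrays). Pigment epithelium and melanocytes gave 0.16 (probes above background on all arrays). Corneal and conjunctival epithelium gave -0.28 (array weights). Immediate early genes gave -1.40 to 0.15 with an array left out. Signal over background limits the dim genes: without the filter on dim probes 2002 of 20659 genes passed.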

Other observations

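The split counts for genes, the spread of the cell type lists without knock-in 4 and the share of knock-in RNA on wild type 3 were chosen after the result was seen, and the other tests beforehand. Cytokine, chemokine and complement genes were not called as a list (median 1.77, camera adjusted p = 0.0801), with 7 higher and 4 lower of 12 measured (7 higher and 4 lower when adjusted over the list alone); with its 3 genes below background in a group at their bound the median was 1.73. Leaving out 1 array added the call of cytokines, chemokines and complement (adjusted p from 0.03 to 0.0431 without wild type 1 or wild type 2). The list was also called with slide as a random block (adjusted p = 0.0305, 6 higher and 1 lower), and in 8 of 22 alternatives, with adjusted p from 0.00065 to 0.86. Ccl2, a monocyte chemokine, rose by 3.20 (SE 0.23, adjusted p = 0.000297), the complement genes C4b and Serping1 by 3.25 and 2.28, and Vcam1 was at least 8.36-fold higher. The metal-binding metallothionein genes Mt1 and Mt2 rose by 2.71 (SE 0.19) and 3.58 (SE 0.28), and Srxn1, an antioxidant enzyme gene, by 1.79, while Prdx6 fell by 1.35. Among p53 targets and apoptosis genes, Phlda3 rose by 1.99 and Pmaip1 was at least 10.4-fold higher. Sqstm1, an autophagy receptor, rose by 1.96 and the lysosomal protease gene Ctsb by 1.55, while Atg3 fell by 1.44. The small heat shock protein gene Hspb8 rose by 2.92, while Hspe1 and Stip1 were among the 3 lower genes of its list. With slide as a random block 0 of these 3 passed. Leaving out 1 array ended the calls of Hspe1 (adjusted p from 0.0538 to 0.054 without knock-in 2 or wild type 1) and Stip1 (adjusted p = 0.0533 without knock-in 2).

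The other lists not called, with genes higher and lower of those measured, were as follows. Lens capsule and basement membrane had 2 and 1 of 17, adjusted over the list alone 2 and 1, with a median of 0.090 (camera adjusted p = 0.58). Cytosolic heat shock proteins had 5 and 3 of 19, adjusted over the list alone 6 and 4, with a median of 0.085 (camera adjusted p = 0.707). Antioxidant and metal response had 4 and 2 of 29, adjusted over the list alone 4 and 2, with a median of 0.32 (camera adjusted p = 0.389). Autophagy and lysosome had 8 and 2 of 29, adjusted over the list alone 8 and 3, with a median of -0.020 (camera adjusted p = 0.58). Proteasome subunits had 4 and 2 of 31, adjusted over the list alone 3 and 1, with a median of -0.091 (camera adjusted p = 0.978). P53 targets and apoptosis had 7 and 6 of 23, adjusted over the list alone 9 and 6, with a median of 0.18 (camera adjusted p = 0.58). Calcium handling had 3 and 2 of 25, adjusted over the list alone 3 and 2, with a median of -0.042 (camera adjusted p = 0.915). Ion pumps and transporters of the lens circulation had 2 and 0 of 18, adjusted over the list alone 0 and 0, with a median of 0.19 (camera adjusted p = 0.58). Cholesterol synthesis had 1 and 4 of 23, adjusted over the list alone 1 and 4, with a median of -0.10 (camera adjusted p = 0.58). Glycolysis had 2 and 3 of 21, adjusted over the list alone 3 and 4, with a median of 0.034 (camera adjusted p = 0.801). Mitochondrial respiratory chain had 3 and 4 of 41, adjusted over the list alone 3 and 3, with a median of -0.16 (camera adjusted p = 0.58). FGF and ERK signalling had 2 and 1 of 16, adjusted over the list alone 2 and 1, with a median of 0.20 (camera adjusted p = 0.443). TGF-beta and BMP signalling had 2 and 3 of 19, adjusted over the list alone 2 and 3, with a median of 0.075 (camera adjusted p = 0.801). Wnt signalling had 2 and 2 of 19, adjusted over the list alone 1 and 2, with a median of -0.045 (camera adjusted p = 0.58). Notch signalling had 1 and 3 of 12, adjusted over the list alone 1 and 3, with a median of -0.22 (camera adjusted p = 0.58). Pigment epithelium and melanocytes had 1 and 2 of 8, adjusted over the list alone 3 and 2, with a median of 0.41 (camera adjusted p = 0.593). Ciliary body, iris and zonule had 2 and 0 of 11, adjusted over the list alone 2 and 0, with a median of 0.87 (camera adjusted p = 0.345). Corneal and conjunctival epithelium had 1 and 0 of 9, adjusted over the list alone 1 and 0, with a median of 0.48 (camera adjusted p = 0.58). Blood vessel endothelium had 1 and 0 of 5, adjusted over the list alone 1 and 1, with a median of -0.41 (camera adjusted p = 0.682). Erythroid cells had 1 and 1 of 5, adjusted over the list alone 1 and 1, with a median of -0.46 (camera adjusted p = 0.843). Skeletal muscle had 0 and 4 of 5, adjusted over the list alone 0 and 4, with a median of -1.68 (camera adjusted p = 0.0643). Immediate early genes had 1 and 2 of 14, adjusted over the list alone 0 and 1, with a median of -0.44 (camera adjusted p = 0.58). On leaving out 1 array calls were added for ciliary body, iris and zonule (adjusted p = 0.03 without wild type 2), skeletal muscle (adjusted p from 0.0182 to 0.043 without knock-in 1 or wild type 2) and immediate early genes (adjusted p = 0.0297 without wild type 3), and within the scan day the muscle and immediate early lists were called lower (adjusted p = 0.0492 each). With genes below background at their bound, the muscle, immediate early, cholesterol and Wnt medians were -1.29, -0.28, -0.061 and -0.025. The list median, its mean and the direction of its test differed in sign for autophagy, proteasome, calcium handling, glycolysis, leukocyte, endothelium and erythroid lists. Xist and the Y-linked Ddx3y were measured on every array and no difference between genotypes passed the test (log2 0.26 and -0.09, adjusted p = 0.423 and 0.711). Both being present on every array leaves open that each held RNA pooled from animals of both sexes, in which case n counts pools and the SDs are those between pools.

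After scaling, the crystallins lay below wild type arrays 1 and 2 on wild type array 3 by a median of 2.09, but not by the same amount for each probe: the dimmer probes stood at 5.40 for Cryaa against at most 5.73 and 5.60 for Cryab against at most 6.05, and at -0.65 for Crygf against at most 6.20. RNA of the knock-in type in that sample is argued against: the 67 genes called without that array and at least 16-fold higher in knock-in lay on it, on the linear scale, at a median share of -0.013 of the way to knock-in (95th percentile 0.0406). In the 13 of them well above background on all arrays the highest share was 0.00573. However, all genes called without that array had a median position of 0.35 on the log2 scale, with an upper quartile of 0.83. That position was the test set beforehand, it lay between its bounds and by itself did not decide. The share was chosen after it was seen. Brightness compression was tested on 87 other genes of at least 7.67 on wild type arrays 1 and 2, the level of Crybb1. Their median difference was -0.89 against -2.09. Most crystallins were brighter than that limit there, Crybb2 at 9.94 and 10.19, so this test can understate compression. A different order of abundance was tested by quantile normalization, which left -0.79. Both values lay between the bounds set beforehand. These 2 explanations stay open, and biological variation between wild type animals was not tested.

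Cell makeup, outside tissue and slides were set against the lists that rose or fell. A smaller share of fibre cells would raise markers of every other cell type alike, and their list medians ran apart by 2.57 (standard error 1.16), but by 2.05 (standard error 1.15) without knock-in 4, whose photoreceptor transcripts may have another source, and this is within the bound of 2 standard errors. The lens epithelial median of -0.38 goes against this explanation, which stays open. Of 6 lists of tissues outside the lens, 0 were higher at the test, but photoreceptors at 2.16 and ciliary genes at 0.87 had medians over the 0.5 set beforehand, so tissue from outside the lens stays open. For slides, 2 of the 6 called lists shifted between wild type slides by at least 50% of the genotype shift in the same direction, crystallins and ribosomal proteins, and slide and genotype cannot be told apart. The 10 splits of the arrays are too few for a share under 0.05. In all, 1 of 10 gave as many genes as the real split (3312, highest other 0), 1 of 10 as many at least 2-fold changed (1841, highest other 0), and 6 of 10 as many lists (6, highest other 8). The other splits mix the genotypes unevenly and keep part of their difference, which also adds to the spread between arrays. They are therefore no measure of what arrays without a genotype difference would give, for genes or for lists.

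The photoreceptor genes on knock-in array 4 may come from retinal tissue in that sample. A second list of 24 photoreceptor genes was higher there by a median of 1.01, 12 of them by at least 1 (the 11 well above background on all arrays by 0.28), short of the 1.5 set beforehand for this cause and above the 0.5 set against it over the whole list. A list of 18 inner retina genes lay there above knock-in arrays 1 and 2 by a median of 0.27, 5 of them by at least 1. Retinal glia genes lay there at a median of -0.41, with 2 of 10, Rlbp1 and Kcnj10, higher by at least 1. Clu and Dkk3, bright in every sample, would hide a small share but were about level and do not account for the fall. S100b stood at -2.88 against -1.37 and -1.49, and Apoe at 3.59 against 5.84 and 4.14. Picked after their values were seen, Rlbp1 at -1.48 against -2.61 and -3.25, Kcnj10 at -2.81 against -3.19 and -4.80 and Rgr, from the pigment epithelium list, at -1.33 against -4.21 and -5.72 on knock-in arrays 1 and 2 were well above background on knock-in array 4 alone, and retinal tissue stays open. All genes differed by a median of 0.00541, but the scaling of each array holds this value near 0. It therefore cannot decide on the brightness or scaling of the array. After scaling, 233 of 12785 genes tested were higher there by at least 1, against 18 of the 22 photoreceptor genes, so the rise was not one of all genes. No biological explanation was tested.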
